A study of Homo sapiens with 15 samples.

How the data were processed

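Small RNA libraries were analysed from 5 human lung cell lines grown for 6 days as multicellular spheroids, with 3 biological replicates per line and 15 libraries in all. HBEC3 is a non-malignant bronchial epithelial line, and H23, H1299, Calu-1 and A549 are lung cancer lines. Each library was assigned to its line and replicate number from the sample titles. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with the QIAseq miRNA kit. The cancer lines were cultured in media with fetal bovine serum and HBEC3 in a bronchial epithelial medium with growth supplements, so that medium and line cannot be separated in any comparison with HBEC3. H23 and H1299 shared a medium, and the media of A549 and Calu-1 differed from it and from each other.

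The values the authors deposited are whole-number read counts per mature miRNA and library, with no normalisation. The submitters' processing notes name cutadapt 1.15, Bowtie2 2.1.0, edgeR 3.4.2 and the build GRCh38.p12, with no role or order. Whether molecular identifiers of the kit were collapsed, whether strand was used in counting, and how reads matching several miRNAs were assigned are not given in the sources used here. A miRNA without reads in a library has no line in that library's table, and the smallest listed count was 1. Some arms whose partner arm was counted, such as miR-192-5p, miR-27a-3p and miR-27b-3p, are in none of the tables, and the reason was not tested. Each table also held 15 lines that name no miRNA. Of these, 13 carry sequence lengths from 16 to 28 nt and tally 2654 reference sequences, and the others carry an aligner name and a sort order, as fields of an alignment header do. These lines were identical in all libraries, equalled 0.097% to 0.332% of the miRNA reads, and were left out of library sizes and tests.

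The miRNA reads per library ranged from 796914 (Calu-1 replicate 3) to 2746402 (A549 replicate 1). Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The low-count filter (filterByExpr by line, minimum count 10, minimum total 15) kept 438 of the 1062 miRNAs detected. Library sizes were scaled with TMM factors. A negative binomial quasi-likelihood model was fitted to all 15 libraries with line as the only factor (10 residual degrees of freedom), since one shared fit estimates the spread from all replicates. Contrasts were tested with edgeR's quasi-likelihood F test, and p-values were adjusted with the Benjamini-Hochberg method within each contrast. A miRNA was called changed at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The comparisons were each cancer line with HBEC3 and each pair of cancer lines, in which the first-named line is the numerator. Series labels give no order of aggressiveness among the lines, so none was assumed.

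Levels are given as TMM-normalised CPM, which need not sum to the same total in each library, as mean ± SD over 3 libraries. A fold against a line with 0 reads in its 3 libraries was computed against a floor of 3 counts over the group and is written as a lower bound. With 1 to 3 reads in a line, the ratio of normalised levels is given with its 95% exact conditional binomial interval. Shares of reads have 95% exact binomial (Clopper-Pearson) intervals. These intervals and floors cover counting error only, because sequenced PCR products need not be independent molecules. Arm shares of miR-10a were compared with two-sided exact permutation tests, which cannot go below 0.1 with 3 libraries against 3.

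The rule for the miRNAs named, and 24 fixed lists of families, clusters and cell-type miRNAs, were set before the data were examined. In each comparison with HBEC3, named miRNAs were the 10 largest positive and 10 largest negative log2 fold changes among called miRNAs whose 3 libraries of one line all lay apart from the 3 of the other and whose mean reached 100 CPM in the higher line. Pairs of cancer lines used the 4 largest each way. The set shared by all 4 cancer lines used the 8 each way with the largest smallest absolute change. Up to 4 of the most abundant members per list were added, with miR-10a-3p, miR-10a-5p, miR-21-5p, miR-210-3p and miR-205-5p in every case. List members matched any arm or genomic copy of a name. The lists were the let-7, miR-200, miR-29, miR-15/16, miR-30 and miR-34/449 families, the miR-17-92 and paralogous clusters, the miR-183/96/182, miR-192/194/215, miR-224/452, 14q32, C19MC, Xq27, HOX and pluripotency clusters, and miRNAs of basal and squamous epithelium, inflammation, hypoxia, neuroendocrine, mesenchymal, haematopoietic, endothelial and muscle cells and of serum. The 16 lists with at least 3 tested members were tested with camera (preset inter-gene correlation 0.01), adjusted over the lists. Camera compares a list with all other miRNAs tested, and it was repeated with an estimated correlation. List medians are given with members at 0 reads in a line and more than 3 in the other set at their bounds. All other members keep their fitted log2 fold change.

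Loci are from the GENCODE annotation of GRCh38, which held a gene for 434 of the 438 tested miRNAs (99.1%). For 26 tested miRNAs a second miRNA gene lies on the opposite strand, and their levels are uncertain because strand handling was not stated. Mature miRNAs of a family that differ by single bases, such as the let-7 members, miR-10a-5p and miR-10b-5p, or miR-199a-3p and miR-199b-3p, are uncertain in the same way where reads match several of them.

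Replicates were compared before averaging. The chi-square statistic per degree of freedom between replicate pairs of a line lay between 8.33 and 950.0, so that no pair differed by as little as sampling noise. Comparisons with the same HBEC3 libraries share their chance values. The overlap of calls was set beside 20 simulations of unchanged lines and beside the overlap of independent lists. The simulated lines were drawn around the mean of these same HBEC3 libraries, so neither comparison measures the effect of shared chance values.

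Alternatives were DESeq2 median-of-ratios, total count, TMMwsp and upper quartile scaling, no low-count filter, a filter at 50 CPM in 3 libraries, a minimum absolute log2 fold change of 1, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the libraries of the lines compared, thinning to the smallest library, each replicate left out in turn, and camera with an estimated correlation and fry for lists. After seeing the data, a count of calls kept under both TMM and total count scaling, the shared set without Calu-1, and 2 other filters for the 14q32 list were added. The scripts were tested on simulated counts with known changes at 3 against 3 libraries. For H23 against HBEC3 (370 miRNAs tested), 86.9% of the 4-fold changes and 38.4% of the 2-fold changes were recovered, and 2.6% of unchanged miRNAs were called. For Calu-1 against HBEC3 (424 tested) these were 85.2%, 31.5% and 2.4%. Of 2-fold changes over 100 CPM in HBEC3, 76.0% were recovered in the H23 simulation and 68.0% in the Calu-1 simulation. The simulated line had the HBEC3 profile, with changes set in equal numbers up and down. These rates therefore do not cover errors from scaling between lines whose profiles differ as much as the real ones. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.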

Results

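The 15 libraries gave 31283948 miRNA reads. Mean reads per library were 2173277 in HBEC3, 2159390 in H23, 2017911 in H1299, 1372881 in Calu-1 and 2704523 in A549 (n = 3 each). Calu-1 was the shallowest and most uneven line, with 796914 to 2157110 reads per library. A total of 1062 miRNAs had reads in at least 1 library, and 228 had reads in all 15. HBEC3 libraries held 440.3 ± 12.7 miRNAs with reads (SD, n = 3), H23 672.0 ± 28.6, H1299 618.7 ± 23.2, Calu-1 383.7 ± 52.6 and A549 607.0 ± 3.6.

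The lines differed in their most abundant miRNA. In HBEC3 it was miR-205-5p, an epithelial miRNA of basal and squamous cells, with 16.8% to 18.8% of reads. The broadly expressed miR-16-5p led in H23 (13.5% to 14.8%), and miR-16-5p or miR-21-5p led in H1299 (14.1% to 14.9%). In A549, miR-21-5p, which is abundant in many carcinomas, took 30.7% to 38.8% of reads. In Calu-1, let-7i-5p took 13.9% and 15% in 2 libraries and 25.9% in replicate 3. The 10 most abundant miRNAs held a mean of 76.8% of reads in HBEC3, 59.9% in H23, 65.1% in H1299, 80.0% in Calu-1 and 72.6% in A549.

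On log2 CPM of the 438 tested miRNAs, libraries lay apart by line, and the first 3 principal components held 47.9%, 19.8% and 13.9% of the variance. Replicates of a line correlated across miRNAs at 0.951 to 0.977 in Calu-1 and at 0.983 to 0.992 in the other lines. Between lines, the mean correlation was lowest for HBEC3 with H23 (0.631) and highest for H1299 with A549 (0.861). These correlations are across miRNAs, which are not independent replicates.

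**Figure D1:**
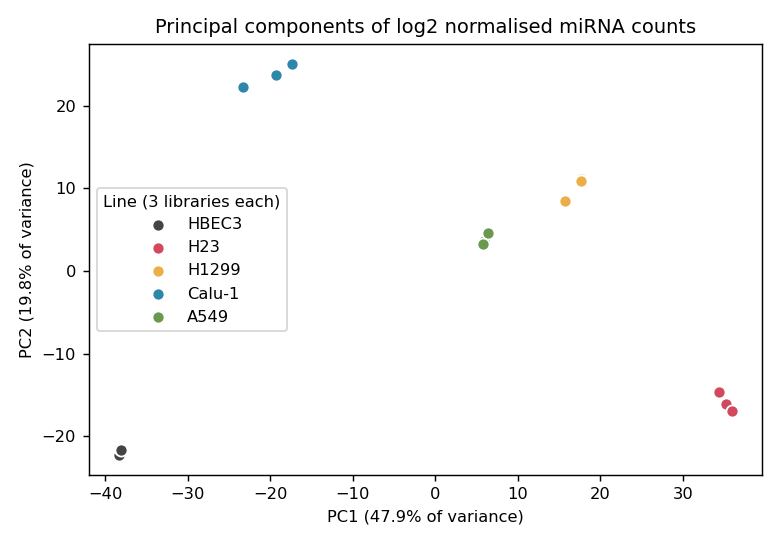
Principal components of log2 CPM over the 438 tested miRNAs, with 1 point per library coloured by cell line and axes giving the percent of variance of each component. The 3 libraries of each line lie together and the 5 lines lie apart.

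Scaling affected the directions below. TMM factors averaged 0.505 ± 0.0249 in HBEC3, 1.97 ± 0.162 in H23, 1.67 ± 0.117 in H1299, 0.569 ± 0.0278 in Calu-1 and 1.07 ± 0.0638 in A549 (SD, n = 3). Scaling by total count alone would raise the log2 fold changes of single miRNAs against HBEC3 by a median of 1.94 in H23, 1.70 in H1299, 0.16 in Calu-1 and 1.07 in A549. In Calu-1, upper quartile scaling would raise them by a median of 0.68 and TMMwsp scaling would change them by a median of -0.31. Changes smaller than these shifts carry a direction only relative to TMM.

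H23, a lung adenocarcinoma line, lost the epithelial miRNAs that dominated HBEC3 and carried a large set of miRNAs from chromosome 14. All 9 tested arms of the miR-200 family, which holds epithelial identity by repressing the ZEB transcription factors, fell (median log2 fold change -9.63, camera adjusted p = 8.03e-09, and 0.00302 with an estimated correlation). All 12 tested arms of the basal and squamous epithelial list fell as well (median -6.16, camera adjusted p = 8.03e-09, and 0.00302 with an estimated correlation). In contrast, all 47 tested arms of the imprinted DLK1-DIO3 cluster at 14q32 rose (median 5.89, camera adjusted p = 1.19e-13, and 0.0197 with an estimated correlation). Adjusted over the list alone, these counts were again 9, 12 and 47. The figure of 47 depends in part on the low-count filter, which 33 of these arms passed only through the H23 libraries, and 17 further detected arms were too scarce to test. In checks chosen after seeing the data, a filter on the other 4 lines left 14 arms, all higher in H23 (camera adjusted p = 1.87e-11, but lost at 0.0771 with an estimated correlation). With no filter, 50 of 64 arms were higher and 0 lower (camera adjusted p = 1.76e-22, and 0.00502 with an estimated correlation).

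Of 438 miRNAs, 311 differed between H23 and HBEC3 by edgeR's quasi-likelihood test, 190 higher and 121 lower in H23. With total count scaling, 313 were higher and 69 lower, and 259 miRNAs were called in the same direction under both scalings. The 3 libraries of one line lay apart from the 3 of the other for 80.6% of miRNAs, against 10% by chance. The squamous and basal miR-205-5p, from its host gene MIR205HG on chromosome 1 (209432133 to 209432242), fell from 346800 ± 10690 normalised CPM in HBEC3 to 0.525 ± 0.516 in H23 (SD, n = 3; log2 fold change -19.16, SE 1.26, edgeR adjusted p = 1e-11). The keratinocyte differentiation miRNA miR-203a-3p fell from 276800 ± 20950 to 188.6 ± 99.5 (log2 -10.52). Its gene on chromosome 14 (104117405 to 104117514) lies opposite MIR203B, so reads of both are uncertain. miR-200c-3p fell from 142100 ± 3240 to 99.5 ± 9.93 (log2 -10.48) and miR-200b-3p from 8658 ± 483 to 1.23 ± 0.683 (log2 -12.78). The other named miRNAs with lower levels in H23 were miR-200a-3p, miR-429 and the minor arms miR-200a-5p, miR-200b-5p, miR-203a-5p and miR-203b-5p. miR-200b-5p had 0 reads in H23 and was at least 729-fold lower.

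Within the 14q32 cluster, miR-127-3p, one of its imprinted placental miRNAs, reached 3318 ± 466 CPM in H23 (SD, n = 3) against 2 reads in all HBEC3 libraries together (ratio 5330, 95% interval 1470 to 44000; edgeR adjusted p = 1.54e-13). miR-409-3p rose from 2.72 ± 1.48 to 1284 ± 65.3 CPM (log2 8.85). HBEC3 had 0 reads of miR-493-5p, miR-493-3p, miR-370-3p, miR-487b-3p, miR-539-3p and miR-136-3p, and H23 exceeded it by at least 920-fold, 470-fold, 247-fold, 217-fold, 192-fold and 123-fold. For miR-432-5p, with 1 read in HBEC3, the ratio was 3530 (95% interval 634 to 140000). The 47 arms came from 37 genes over 213.3 kb of chromosome 14 (100852390 to 101065667). With the arms too scarce to test, the 64 detected arms of the list took 154065 reads in H23, against 114 in HBEC3.

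**Figure D2:**
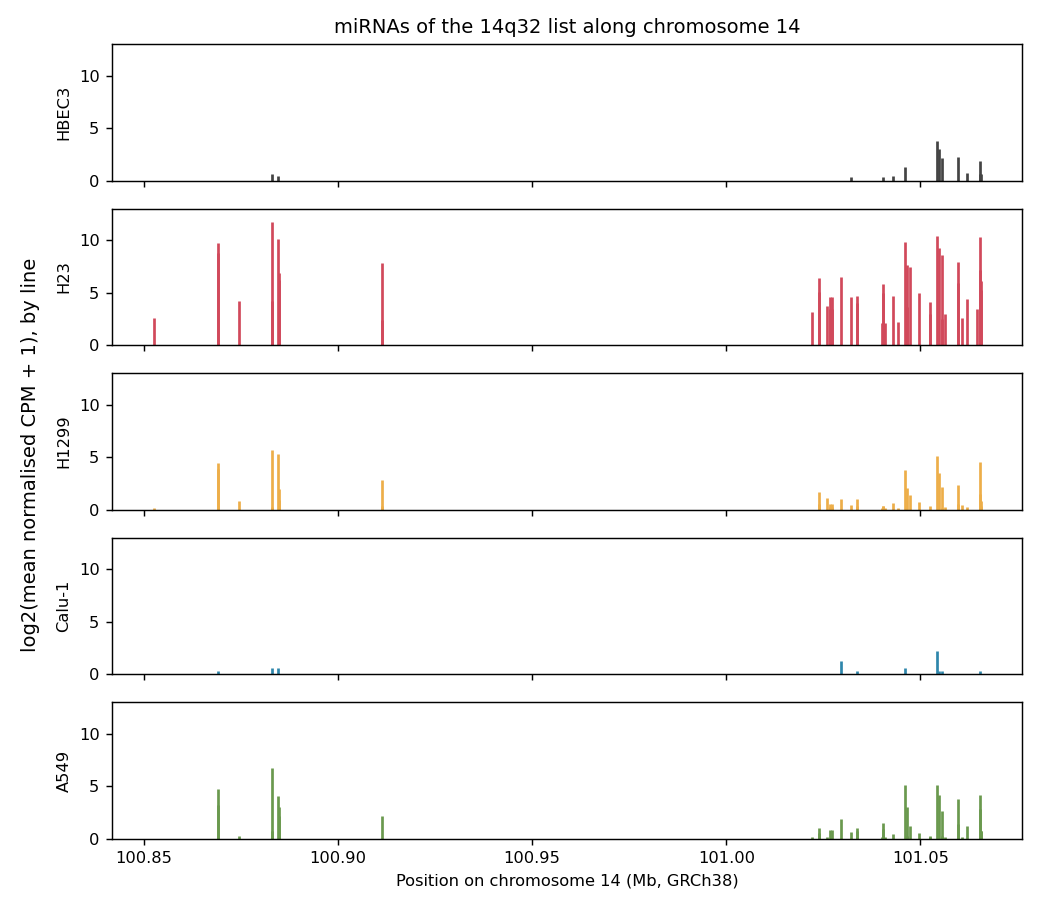
Mean normalised CPM (log2 of CPM + 1) of the 47 tested miRNAs of the 14q32 list at their GRCh38 positions on chromosome 14, with 1 panel per cell line and 1 bar per miRNA and gene copy. miR-329-3p, miR-329-5p and miR-376a-5p are drawn at each of their gene copies with the same value. Arms of the same gene share a position, so the taller bar covers the shorter. Bars in H23 stand above those of the other 4 lines along the cluster.

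Of the 10 largest rises in H23, 2 lay outside 14q32. miR-105-5p and miR-767-5p, which share an intron of GABRA3 on the X chromosome (152392219 to 152394492), had 0 reads in HBEC3 and were at least 227-fold and 217-fold higher. miR-196a-5p, encoded beside HOX genes on chromosomes 12 and 17, rose from 30.7 ± 5.75 to 8081 ± 823 CPM (log2 8.03, edgeR adjusted p = 7.36e-14). Within the HOX list, 3 of 7 arms rose (miR-196a-5p, miR-196b-5p and miR-615-3p), and miR-10a-5p fell by 1.71 on the log2 scale but was higher by 0.25 with total count scaling. That list did not pass (camera adjusted p = 0.34). Among let-7 arms, whose family marks differentiated cells, 7 of 14 fell and 2 rose (let-7i-5p and let-7d-5p), which did not pass as a list (median -1.12, camera adjusted p = 0.0642). The let-7 median was 0.78 with total count scaling, with 7 arms higher and 4 lower. The abundant growth-associated miR-21-5p fell by 1.28 with TMM and rose by 0.67 with total count scaling. The hypoxia-induced miR-210-3p was not called with TMM (log2 -0.36, edgeR adjusted p = 0.595) but was higher with total count scaling (1.61, edgeR adjusted p = 0.0168). With only the H23 and HBEC3 libraries in the fit it was lower instead (-0.455, edgeR adjusted p = 0.0116).

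H1299, a large cell carcinoma line from a lymph node, had lower levels of epithelial miRNAs and of most let-7 arms. All 9 tested miR-200 family arms fell (median -9.92, camera adjusted p = 2.42e-09, and 0.00146 with an estimated correlation). All 12 basal and squamous arms fell (median -5.48, camera adjusted p = 3.44e-07, and 0.00448 with an estimated correlation), but the fall of miR-221-3p (-0.74) reversed to 1.00 with total count scaling. It was also not called without HBEC3 replicate 1, 2 or 3 (edgeR adjusted p = 0.222, 0.273 and 0.209) or H1299 replicate 2 (0.163), nor under 4 other scalings and filters. Of 14 let-7 arms, 12 fell, and the rare let-7a-2-3p rose (median -3.26, camera adjusted p = 2.53e-06, and 0.023 with an estimated correlation). Of 7 HOX cluster arms, 5 rose (median 3.94, camera adjusted p = 0.00256), a call lost with an estimated correlation (adjusted p = 0.211). Adjusted over the list alone, the counts were the same.

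The edgeR test called 300 of 438 miRNAs, 178 higher and 122 lower in H1299. Total count scaling gave 293 higher and 80 lower, and 258 were called in the same direction under both. Libraries lay apart for 75.8% of miRNAs (10% by chance). The let-7 fall was deepest for let-7b-5p, from 102400 ± 8343 to 1122 ± 133 CPM (SD, n = 3; log2 -6.51, edgeR adjusted p = 6.85e-14), and let-7a-5p fell by 2.33 from 211900 ± 17770 CPM. miR-200c-3p, from the MIR200CHG locus on chromosome 12 (6963699 to 6963766), fell to 16.5 ± 14.6 CPM (log2 -13.04) and its neighbour miR-141-3p to 3.09 ± 1.76 (log2 -11.80). miR-205-5p fell to 22.6 ± 33.7 CPM, with an SD above its mean (log2 -13.87). miR-135b-5p, abundant in epithelia, fell by 9.67. The minor arms miR-200c-5p, miR-200b-5p and miR-141-5p had 0 reads and were at least 805-fold, 572-fold and 551-fold lower.

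Among miRNAs higher in H1299, miR-767-5p and miR-105-5p of the X chromosome led, with 0 reads in HBEC3 and at least 539-fold and 294-fold differences. The HOX cluster miRNAs miR-615-3p (log2 6.91, SE 0.604, edgeR adjusted p = 3.78e-09) and miR-196a-5p (6.72, to 3252 ± 437 CPM) followed. miR-155-5p, an NF-kB-responsive miRNA of immune activation from MIR155HG on chromosome 21 (25573980 to 25574044), rose from 20 ± 6.44 to 1521 ± 461 CPM (log2 6.24). miR-100-3p (6.51), miR-301a-5p (5.93), miR-450b-5p (5.06), miR-935 (5.02) and miR-301a-3p (5.01) were the other named miRNAs. Of the 7 arms of the miR-34 and miR-449 family, which pairs DNA-damage-induced with multiciliated-cell miRNAs, 5 fell and miR-449a and miR-449c-5p rose (camera adjusted p = 0.102). The main member, miR-34a-5p, fell from 15450 ± 1376 to 177.7 ± 18.9 CPM (log2 -6.44). miR-21-5p (log2 -0.19) and miR-210-3p (0.36) were not called with TMM (edgeR adjusted p = 0.542 and 0.595) but were higher by 1.52 and 2.06 with total count scaling (edgeR adjusted p = 7.84e-06 and 0.00391).

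Calu-1, a line from an epidermoid lung carcinoma, had lower levels of all miR-200 arms and of most basal and squamous arms. The NF-kB-responsive miR-155-5p and miR-146a-5p were its largest rises among the miRNAs of at least 100 CPM named for this comparison. The inflammation list did not pass (2 of 6 arms higher and 3 lower, 3 and 3 adjusted over the list alone, camera adjusted p = 0.306). All 9 miR-200 family arms fell (median -6.30, camera adjusted p = 4.1e-10, and 0.00638 with an estimated correlation). In the basal and squamous list, 9 of 12 arms fell and miR-221-3p, a growth-associated miRNA, rose by 1.26 (list median -2.45, camera adjusted p = 0.000701, and 0.0223 with an estimated correlation). Of the 7 arms of the miR-34 and miR-449 family, 4 fell and 0 rose (median -3.92, camera adjusted p = 0.00596, and 0.0449 with an estimated correlation). The 4 were miR-34a-5p, miR-34b-5p, miR-34c-5p and miR-34c-3p. Counts adjusted over the list alone were the same.

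The edgeR test called 190 of 438 miRNAs, 96 higher and 94 lower in Calu-1, and 180 of them were called in the same direction with total count scaling. The split was 139 higher and 67 lower with upper quartile scaling, and 78 and 119 with TMMwsp scaling. Libraries lay apart for 45% of miRNAs (10% by chance). miR-155-5p rose from 20 ± 6.44 to 9080 ± 1254 CPM (SD, n = 3; log2 8.82, SE 0.439, edgeR adjusted p = 4.23e-13). miR-146a-5p, which restrains NF-kB signalling and lies on chromosome 5 (160485352 to 160485450), rose from 979.8 ± 119.9 to 52640 ± 36550 CPM (log2 5.75, edgeR adjusted p = 2.17e-10), with the spread set by unequal replicates. let-7i-5p, from chromosome 12 (62603686 to 62603769), rose from 9232 ± 619 to 318700 ± 101400 CPM (log2 5.11). The let-7 list went both ways, with 7 arms up and 2 down (let-7b-5p and let-7c-5p), and did not pass (camera adjusted p = 0.0877). let-7b-5p was not called with upper quartile scaling (edgeR adjusted p = 0.0695). miR-125b-1-3p (5.31), miR-100-3p (5.17), miR-139-5p (4.56), miR-625-3p (4.13), miR-29b-1-5p (3.97), miR-196a-5p (3.95) and miR-10a-5p (3.83) were also higher.

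Lower levels in Calu-1 were led by miR-205-5p (6.95 ± 5.34 CPM, log2 -15.89), miR-203a-3p (9.64 ± 9.53 CPM, log2 -14.88), miR-141-3p (log2 -10.22) and miR-200c-3p (log2 -8.67), followed by miR-200c-5p (-6.57) and miR-429 (-6.32). miR-203b-5p and miR-203a-5p had 0 reads, at least 480-fold and 202-fold lower. With 1 read each in Calu-1, miR-483-5p had a ratio of 0.00146 (95% interval 3.69e-05 to 0.00816) and miR-187-3p of 0.00155 (3.93e-05 to 0.00868). The HOX list went both ways: miR-10a-5p, miR-10a-3p and miR-196a-5p rose and miR-196b-5p fell (camera adjusted p = 0.306). Its median was -0.25 while its mean was 0.18 and the test pointed up. No 14q32 arm was higher in Calu-1 and 4 of 47 were lower, 1 when adjusted over the list alone, and the list held 20 reads in its 3 libraries (camera adjusted p = 0.918). The result for miR-210-3p rested on replicate 3: log2 0.58 with all libraries (edgeR adjusted p = 0.466) and -1.73 without it (edgeR adjusted p = 9.91e-05). miR-21-5p was not called with all libraries (log2 0.36, edgeR adjusted p = 0.323) but was without Calu-1 replicate 3 (0.55, edgeR adjusted p = 0.0285) and with upper quartile scaling (1.03, edgeR adjusted p = 0.00183).

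A549, an adenocarcinoma line of alveolar type, had lower levels of epithelial miRNAs and higher levels of miR-194 arms and of the minor arm miR-192-3p, from endodermal miRNA genes. All 9 miR-200 family arms fell (median -6.87, camera adjusted p = 2.31e-10, and 0.00304 with an estimated correlation). In the basal and squamous list 10 of 12 arms fell, 11 when adjusted over the list alone, and miR-27b-5p rose (median -1.98, camera adjusted p = 2.71e-05, and 0.0205 with an estimated correlation). With total count scaling 7 of its arms fell, and miR-23b-3p reversed to 0.28. All 3 tested arms of the miR-192 and miR-194 list (miR-192-3p, miR-194-3p and miR-194-5p) rose (median 5.66, camera adjusted p = 0.00377), a call lost with an estimated correlation (adjusted p = 0.0659). miR-192-5p and miR-215-5p are listed in none of the count tables, so the list rests on miR-194-5p and 2 minor arms. All 7 HOX cluster arms rose (median 3.74, camera adjusted p = 0.00266), also lost with an estimated correlation (adjusted p = 0.25). Of the 7 arms of the miR-34 and miR-449 family 5 fell, 6 when adjusted over the list alone, and miR-449c-5p rose (median -2.64, camera adjusted p = 0.00967), lost with an estimated correlation (adjusted p = 0.0633).

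**Figure D3:**
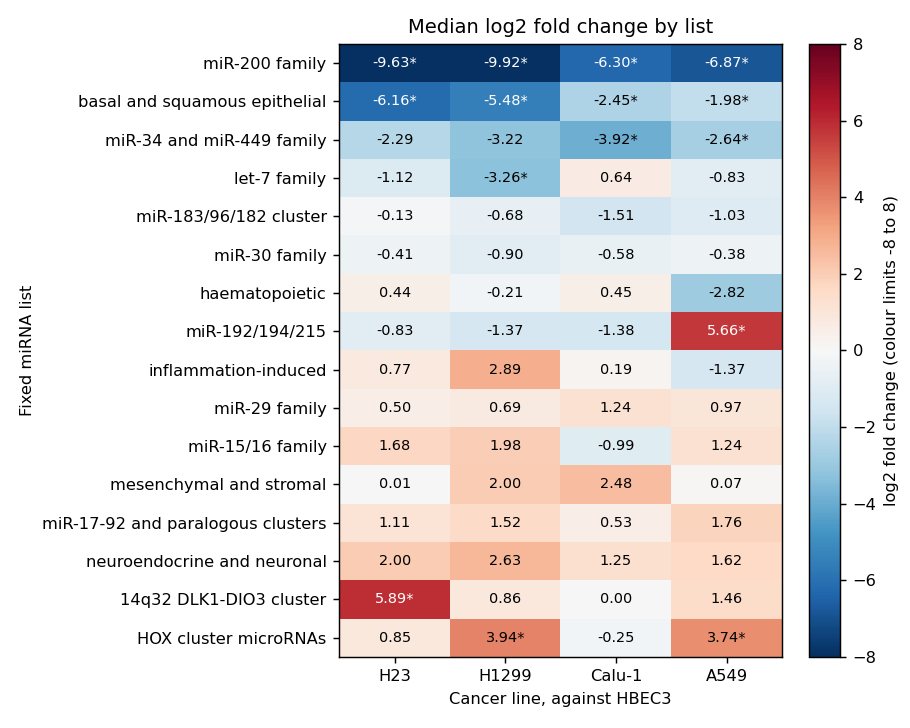
Median log2 fold change of each tested list (vertical) in each cancer line against HBEC3 (horizontal), with colour limits at -8 and 8. Members with 0 reads in a line and more than 3 in the other are set at their bounds. An asterisk marks a camera adjusted p under 0.05, and with total count scaling the let-7 medians of H23 and A549 turn from -1.12 to 0.78 and from -0.83 to 0.25.

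The edgeR test called 286 of 438 miRNAs, 172 higher and 114 lower in A549. Total count scaling gave 247 higher and 55 lower, and 227 kept their direction under both. Libraries lay apart for 70.8% of miRNAs (10% by chance). miR-194-5p, a miRNA of intestinal and hepatic epithelium, rose from 109.1 ± 18.96 to 5498 ± 1419 CPM (SD, n = 3; log2 5.66, SE 0.355, edgeR adjusted p = 1.49e-11). Its partner miR-192-3p rose from 1.21 ± 0.486 to 187.0 ± 28.9 (log2 7.21). miR-196a-5p (6.22), miR-335-3p (5.37), the neural miR-9-3p (5.36), miR-194-3p (5.23), miR-582-3p (5.19), miR-374a-3p (4.92) and miR-935 (4.68) were also higher. miR-127-3p of 14q32, with 2 reads in HBEC3, had a ratio of 173 (95% interval 47.6 to 1430). miR-21-5p rose from 91710 ± 3564 to 322500 ± 55310 CPM (log2 1.81, edgeR adjusted p = 1.07e-05).

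Losses in A549 were led by miR-205-5p (2.41 ± 0.572 CPM, log2 -17.10), miR-203a-3p (4.55 ± 2.06 CPM, log2 -15.87) and miR-708-5p (from 2948 ± 65.5 to 3.30 ± 1.76 CPM, log2 -9.80). miR-203b-5p and miR-203a-5p had 0 reads, at least 1780-fold and 747-fold lower. miR-483-5p (-9.17), miR-200c-3p (-8.78), miR-187-3p (-8.32) and miR-200b-5p (-8.08) followed, and miR-598-3p, with 2 reads in A549, had a ratio of 0.0022 (95% interval 0.000266 to 0.00802). Of 14 let-7 arms, 9 fell and let-7i-5p and let-7i-3p rose (median -0.83, camera adjusted p = 0.0736), and with total count scaling the median was 0.25, with 4 arms higher and 3 lower. miR-210-3p was not called (log2 1.31, edgeR adjusted p = 0.0585) but passed in 8 of the alternatives, among them total count scaling (2.39, edgeR adjusted p = 0.00158), TMMwsp scaling (1.36, 0.046), no low-count filter (1.32, 0.00125), limma-voom (1.28, 0.0446) and A549 replicate 1 left out (1.51, 0.0439). The smallest of these adjusted p-values came with only the A549 and HBEC3 libraries in the fit (log2 1.28, edgeR adjusted p = 0.000322).

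**Figure D4:**
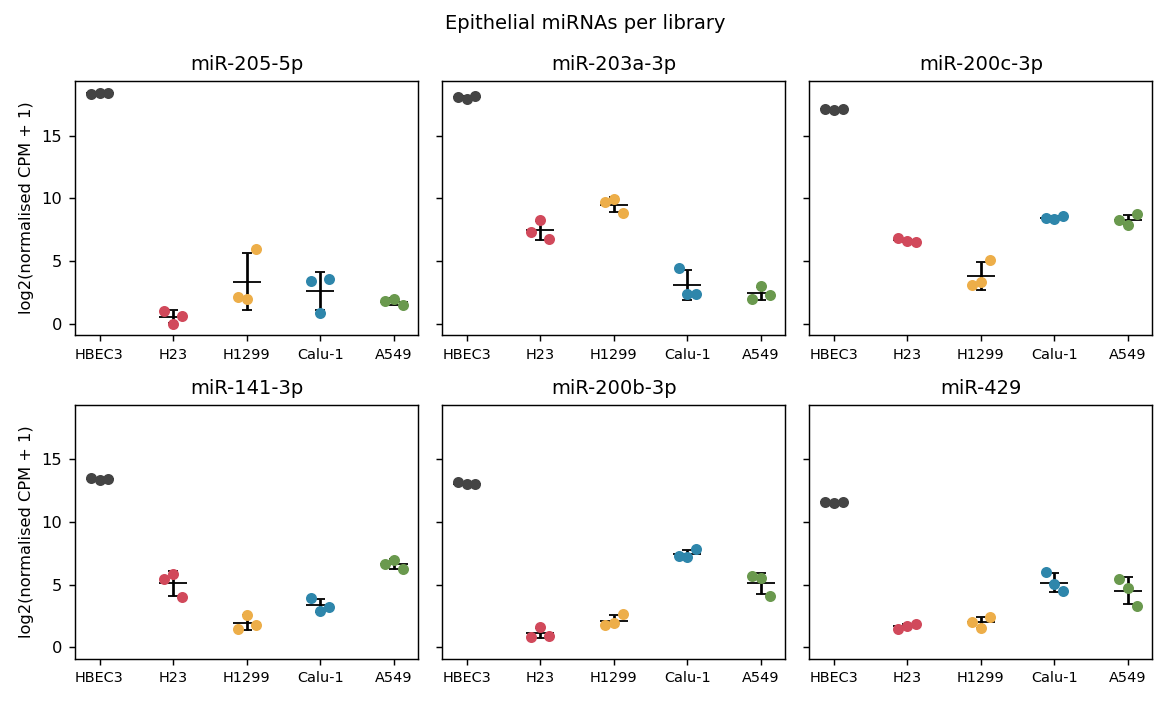
log2 of normalised CPM + 1 of 6 epithelial miRNAs in each library, by cell line, with bars for the mean ± SD of 3 libraries. HBEC3 libraries lie above all libraries of the 4 cancer lines in each panel.

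Across the cancer lines, 95 miRNAs differed from HBEC3 in the same direction in all 4, 39 higher and 56 lower. Lower in all were miR-205-5p, miR-203a-3p, miR-200c-3p, miR-141-3p, miR-203b-5p, miR-203a-5p, miR-200c-5p and miR-187-3p, whose smallest change among the 4 lines was between -13.87 (miR-205-5p) and -6.57 (miR-200c-5p). Higher in all were miR-196a-5p (smallest log2 change 3.95), miR-92b-3p (3.56), miR-7-5p (3.41), miR-3529-3p (3.38), miR-1180-3p (2.80), miR-421 (2.62) and miR-301a-5p (2.30). miR-767-5p, ranked first by the fitted values that the rule uses, had 0 reads in HBEC3 and 10 in Calu-1, where it was at least 4.67-fold higher. All 16 were also called with total count scaling. miR-7-5p and miR-3529-3p lie on opposite strands of one locus and had near-equal reads, so their levels are uncertain. The same holds for miR-374b-5p and miR-374c-3p (higher in all) and for miR-103a-3p and miR-103b (lower in all). miR-365a-3p and miR-365b-3p, both lower in all, also changed nearly alike (smallest absolute log2 change 0.954 and 0.892). If the members of such pairs share reads, the set holds fewer than 95 separate miRNAs, which was not tested. With total count scaling 62 were higher and 31 lower in all 4 lines, and 39 and 31 were in both sets. With upper quartile scaling 52 were higher and 42 lower. Simulated unchanged lines gave 0 shared miRNAs in each of 20 simulations, and independent lists of the same sizes would share 6.6 higher and 1.9 lower. The simulated lines were drawn around the mean of the same 3 HBEC3 libraries, so a count near 0 was built in and says nothing about shared controls. The 3 HBEC3 libraries cannot be split into parts of at least 2, so the effect of shared controls was not tested.

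The series title names miR-10a-3p, the minor arm of MIR10A, which lies in the HOXB cluster on chromosome 17 (48579838 to 48579947, minus strand) inside HOXB3 and HOXB4. It was scarce throughout: HBEC3 held 2 reads, both in replicate 2, H23 held 7, H1299 868, Calu-1 56 and A549 200 in 3 libraries each. Normalised levels were 0.57 ± 0.987 CPM in HBEC3 (SD, n = 3), 0.57 ± 0.206 in H23, 88.5 ± 31 in H1299, 21.6 ± 11.4 in Calu-1 and 23.3 ± 6.70 in A549. The ratio to HBEC3 was 141 in H1299 (95% interval 39.0 to 1170), 39.4 in Calu-1 (10.4 to 334) and 38.0 in A549 (10.4 to 316), with edgeR adjusted p = 8.75e-09, 1.08e-05 and 3.69e-06. All 3 libraries of each of these lines lay above all HBEC3 libraries. In H23 the ratio was 0.894 (0.17 to 8.82; log2 -0.13, edgeR adjusted p = 0.929), which turned to log2 1.65 with total count scaling (edgeR adjusted p = 0.137), so that no difference was detectable at this depth.

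The major arm, miR-10a-5p, was also higher in these 3 lines than in HBEC3 (1279 ± 49.5 CPM), with 19600 ± 895 in H1299, 18180 ± 6708 in Calu-1 and 15720 ± 4611 in A549 (log2 3.94, 3.83 and 3.62; edgeR adjusted p = 1.32e-10, 3.82e-10 and 5e-10). H23 held 391.5 ± 31.2 CPM. Between cancer lines, miR-10a-3p was lower in H23 than in H1299 (log2 -7.20), Calu-1 (-5.24) and A549 (-5.28), with edgeR adjusted p = 6.25e-10, 1.52e-07 and 6.41e-08. It was higher in H1299 than in Calu-1 (1.97, edgeR adjusted p = 0.000568) and A549 (1.93, edgeR adjusted p = 0.000378), and Calu-1 and A549 differed by -0.04 (edgeR adjusted p = 0.974). The 3p arm made up 0.0475% of the pooled miR-10a reads in HBEC3 (exact 95% interval 0.00575% to 0.171%), 0.14% in H23 (0.0565% to 0.289%), 0.435% in H1299 (0.407% to 0.465%), 0.119% in Calu-1 (0.0896% to 0.154%) and 0.148% in A549 (0.128% to 0.17%). These intervals cover counting error only and not the spread between libraries. In H1299 the libraries had 0.457%, 0.597% and 0.294% (SD 0.152), a wider range than its interval. Against HBEC3, the mean share was higher by 0.404 points in H1299 (exact permutation p = 0.1, the smallest possible), 0.0983 in H23 (0.2), 0.0675 in Calu-1 (0.3) and 0.104 in A549 (0.2). Without HBEC3 replicate 2 the differences in share were 0.143 in H23, 0.449 in H1299, 0.113 in Calu-1 and 0.149 in A549, and without HBEC3 replicate 1 or 3 they were 0.0756, 0.381, 0.0448 and 0.0809. Without replicate 2 no control read of miR-10a-3p remained, so that its fitted log2 changes (3.57 in H23, 11.04 in H1299, 8.77 in Calu-1 and 8.77 in A549) are not folds between measured levels.

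**Figure D5:**
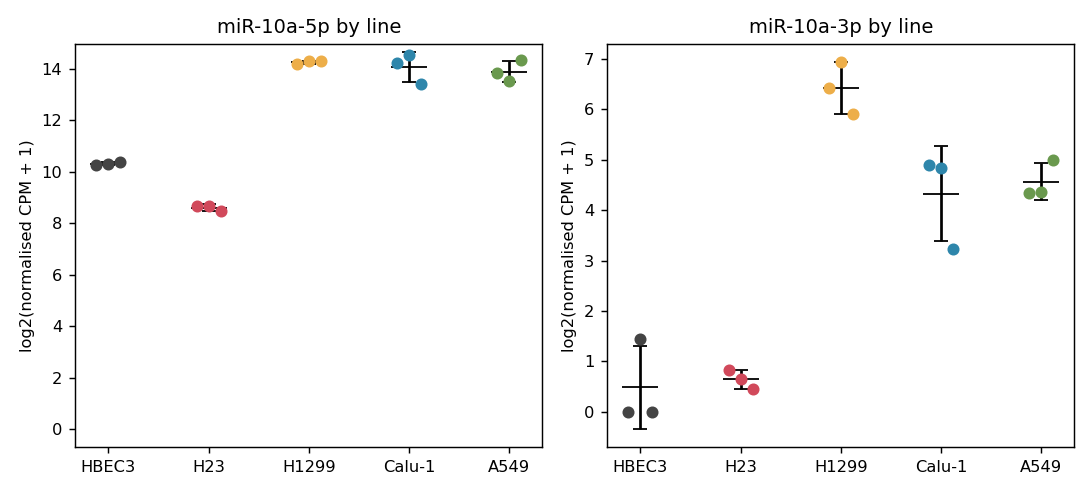
log2 of normalised CPM + 1 of miR-10a-5p (left) and miR-10a-3p (right) in each library, by cell line, with bars for the mean ± SD of 3 libraries. Both arms lie higher in H1299, Calu-1 and A549 than in HBEC3, whose only 3p reads are in replicate 2.

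The cancer lines were also compared with each other. H23 stood apart by 14q32, where all 47 arms were higher in H23 than in each other cancer line. The median was 5.37 against H1299 (camera adjusted p = 2.42e-26, and 1.33e-05 with an estimated correlation). It was 5.00 against A549 (2.77e-24, and 0.00856) and 4.64 against Calu-1 (8.85e-15, lost at 0.0853). The value against Calu-1 is a lower bound, because many arms had 0 reads there and were set at their bounds. The list held 20 reads in Calu-1, 2525 in H1299 and 2785 in A549, so these medians do not rank the lines. On the 14 arms kept by a filter on the other 4 lines, all were higher in each pair, but only the result against H1299 passed with an estimated correlation (0.00249; 0.0557 against A549 and 0.0846 against Calu-1). miR-127-3p held 3318 ± 466 CPM in H23 (SD, n = 3), 51.4 ± 13.4 in H1299, 105.0 ± 16.1 in A549 and 2 reads in Calu-1. H1299 carried less let-7 than Calu-1 and A549: 12 of 14 arms were lower than in Calu-1 (camera adjusted p = 1.3e-10, and 0.00469 with an estimated correlation) and 12 were lower than in A549, with 1 higher (3.73e-05, and 0.0489). These became 10 lower and 2 higher, and 11 lower and 2 higher, with total count scaling. Against Calu-1, 13 let-7 arms were lower in H23 (2.22e-06, and 0.0355), but only 8 with total count scaling, while 4 were then higher. Calu-1 exceeded A549 in 10 let-7 arms (1.56e-05, lost at 0.0589), but with total count scaling in 8, while 3 were lower.

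H23 and H1299 differed in 262 miRNAs (143 higher, 119 lower in H23). The split was 160 and 97 with total count scaling, 125 and 150 with upper quartile scaling, and 137 and 137 with TMMwsp scaling. The 14q32 miRNAs miR-539-3p (log2 6.74), miR-485-3p (6.70), miR-409-5p (6.24) and miR-381-3p (6.14) were higher in H23. miR-155-5p (-7.77), miR-100-3p (-6.50), miR-125b-5p (-5.91, edgeR adjusted p = 2.46e-13), a miRNA of stem and mesenchymal cells, and miR-10a-5p (-5.65) were lower. H23 and Calu-1 differed in 278 miRNAs (168 higher, 110 lower; 304 and 52 with total count scaling, 120 and 148 with upper quartile scaling). miR-493-3p, miR-154-5p, miR-370-3p and miR-487b-3p had 0 reads in Calu-1 and were at least 334-fold, 187-fold, 176-fold and 154-fold higher in H23. miR-146a-5p (-13.36, edgeR adjusted p = 2.94e-14), miR-155-5p (-10.35), miR-138-5p (-7.79) and miR-125b-5p (-7.38) were lower. H23 and A549 differed in 263 miRNAs (133 higher, 130 lower; 200 and 65 with total count scaling). miR-199b-5p (7.78), a fibroblast miRNA, miR-539-3p (7.04) and miR-409-3p (6.25) were higher in H23, and so was miR-598-3p (ratio 683, 95% interval 189 to 5640). miR-1299 (-8.92), miR-99a-5p (-8.04), miR-138-5p (-7.80) and miR-192-3p (-6.60) were lower.

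H1299 and Calu-1 differed in 247 miRNAs (144 higher, 103 lower in H1299; 266 and 53 with total count scaling, 122 and 132 with upper quartile scaling). miR-615-3p was at least 147-fold higher in H1299, and miR-196b-5p (ratio 480, 95% interval 86.0 to 18900), miR-105-5p (312, 86.4 to 2580) and miR-767-5p (log2 6.81) were higher too. miR-146a-5p (-11.45), let-7i-5p (-7.73, edgeR adjusted p = 5.01e-15), miR-708-5p (-7.72) and miR-138-5p (-6.54) were lower. H1299 and A549 differed in 242 (111 higher, 131 lower; 177 and 90 with total count scaling). miR-425-3p (7.50), miR-155-5p (7.43) and miR-203a-3p (7.34) were higher in H1299, with miR-598-3p at a ratio of 1110 (308 to 9190). miR-194-5p (-7.02), miR-194-3p (-6.82), miR-192-3p (-6.76) and miR-138-5p (-6.55) were lower. Calu-1 and A549 differed in 235 (89 higher, 146 lower; 56 and 237 with total count scaling, 127 and 107 with upper quartile scaling). miR-146a-5p (11.10), miR-155-5p (10.01) and miR-708-5p (8.20) were higher in Calu-1, with miR-598-3p at a ratio of 784 (216 to 6490). miR-194-5p was lower (-7.58), and so were miR-196b-5p (ratio 0.000985, 2.49e-05 to 0.00549), miR-192-3p (0.00228, 5.77e-05 to 0.0127) and miR-1299 (0.00487, 0.000589 to 0.0176). Across these 6 pairs, libraries lay apart for 55.3% (Calu-1 and A549) to 69.9% (H23 and H1299) of miRNAs, against 10% by chance.

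Further lists separated pairs of cancer lines. All 3 tested arms of the miR-192 and miR-194 list were lower in H23, H1299 and Calu-1 than in A549 (camera adjusted p = 0.0033, 0.000359 and 0.00129; with an estimated correlation 0.108, 0.0489 and 0.0789). Residual miR-200 family levels were lower in H1299 than in Calu-1 (9 of 9 arms, camera adjusted p = 0.000314, and 0.0196 with an estimated correlation) and A549 (8 of 9, 0.00457, and 0.0489), with 7 arms in each case under total count scaling. In H23, 6 miR-200 arms were lower than in Calu-1 and 1 was higher (0.00712, lost at 0.0853), and 7 were lower than in A549 (0.0372, lost at 0.2). Under total count scaling 5 were lower and 1 higher than in Calu-1, and 4 lower and 1 higher than in A549. Basal and squamous arms were lower in H23 than in Calu-1 (8 of 12, with 1 higher; 0.00441, lost at 0.0853) and A549 (7 of 12, with 1 higher; 0.0372, lost at 0.2), with 7 lower and 2 higher in each case under total count scaling. Mesenchymal arms were lower in H23 than in Calu-1 in 7 of 13 cases and higher in 2 (0.023, lost at 0.407), but 5 were higher with total count scaling. In addition, 6 of 7 HOX arms were higher in H1299 than in Calu-1 (0.0138, lost at 0.334).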

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

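The miRNAs given here were picked by their values: named miRNAs called in opposite directions against HBEC3 in 2 cancer lines, under both TMM and total count scaling, with all libraries of the higher and lower line apart, at least 100 CPM in the higher one, and an edgeR adjusted p under 0.05 for the difference. The restriction to both scalings and to named miRNAs was set after the data were seen. It gave 18 miRNAs, with edgeR adjusted p for the difference from 5.01e-15 (let-7i-5p) to 7.07e-09 (miR-425-3p). Calu-1 was the higher line in 6 of them and the lower line in 6. With 3 libraries per line, no check of single libraries within a line was made.

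Among these, 4 were high in Calu-1 and low in H23, although the inflammation list went both ways between these lines (camera adjusted p = 0.841). miR-146a-5p differed by 13.36 on the log2 scale, with 52640 ± 36550 CPM in Calu-1 (SD, n = 3), 979.8 ± 119.9 in HBEC3 and 4.98 ± 1.51 in H23. miR-125b-5p differed by 7.38, miR-100-5p, encoded beside let-7a-2, by 6.84, and miR-221-3p by 5.13. let-7i-5p (7.73) and let-7f-5p (4.44) were high in Calu-1 and low in H1299.

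H23 exceeded and Calu-1 fell below HBEC3 for the 14q32 miRNAs miR-154-5p and miR-382-5p (8.71) and for the endothelial miR-126-3p (5.95). miR-154-5p had 0 reads in Calu-1, so its difference is a lower bound (log2 of at least 7.54). The lower call of miR-154-5p in Calu-1 was lost without Calu-1 replicate 2 (edgeR adjusted p = 0.0582). That of miR-382-5p was lost without Calu-1 replicate 2 (0.133), after thinning (0.113) and with upper quartile scaling (0.109). A549 exceeded and Calu-1 fell below it for the HOX cluster miR-196b-5p (9.82), the endodermal miR-194-5p (7.58) and the neural miR-9-3p (6.79). miR-196b-5p had 1 read in Calu-1 (ratio to A549 0.000985, 95% interval 2.49e-05 to 0.00549). The lower call of miR-9-3p in Calu-1 was lost without HBEC3 replicate 2 (edgeR adjusted p = 0.08) or Calu-1 replicate 2 (0.108), after thinning (0.218), with upper quartile scaling (0.28), with no filter (0.105) and with limma-voom (0.056). A549 exceeded and H23 fell below it for miR-1299 (8.92) and miR-138-5p (7.80).

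Among the rest, H1299 was the higher and A549 the lower line for miR-598-3p (9.84) and miR-425-3p (7.50). miR-598-3p had 2 reads in A549 (ratio 1110, 95% interval 308 to 9190). The erythroid miR-486-5p was high in H23 and low in A549 (4.52), and miR-29c-3p, which represses collagens, was high in A549 and low in H1299 (4.25). The higher call of miR-29c-3p in A549 was lost with DESeq2 (adjusted p = 0.0501) and without HBEC3 replicate 2 (edgeR adjusted p = 0.0606), HBEC3 replicate 3 (0.0622) or A549 replicate 2 (0.0924). No cause was tested for any of these 18 differences.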

How the results depend on the processing

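The calls under both scalings and the shared set without Calu-1 were added after the data were seen. Of the values for counts of calls, shared sets, lists and miR-10a, 419 were unchanged in kind, 19 moved and 6 reversed. A count was taken as unchanged if its total stayed within 1.5-fold, whatever its split into higher and lower. Splits could turn within that limit. H23 against Calu-1 went from 168 higher and 110 lower to 120 and 148 with upper quartile scaling. The 6 reversals were all of miR-10a-3p in H23 against HBEC3. Of 5368 values for single miRNAs, 5213 were the same, 114 weaker, 12 stronger and 29 reversed. With a replicate left out, called miRNAs against HBEC3 ranged from 291 to 307 in H23, from 280 to 296 in H1299, from 163 to 200 in Calu-1 and from 253 to 273 in A549.

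The filter at 50 CPM tests fewer miRNAs and gave 196 calls for H23 and 197 for H1299 against HBEC3, 166 for H23 against H1299, 151 for H23 against A549 and 157 for H1299 against A549. The shared set of 39 higher and 56 lower miRNAs became 62 and 31 with total count scaling, and 106 and 76 without Calu-1, which asks for 3 lines instead of 4. With the replicate number as a block the total was 92.

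For miR-10a-3p in H23 against HBEC3 (-0.13), the sign depended on the setting: 1.645 with total count scaling, 0.002 with no filter, 0.135 with the 50 CPM filter, 2.144 after thinning, and -0.80 to 3.57 with a replicate left out. In H1299 it was 6.67 to 11.04 in all settings (highest adjusted p = 1.52e-06), in Calu-1 4.40 to 8.77 (0.000864) and in A549 4.40 to 8.77 (0.000335).

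Lists passing in H23, H1299, Calu-1 and A549 were 3, 4, 3 and 5. With no filter, which tests more members, they were 7, 8, 7 and 10, and with fry, which does not compare a list with other miRNAs, 12, 14, 12 and 13. Calu-1 had 5 with TMMwsp scaling and 3 to 5 with a replicate left out, and A549 had 2 with an estimated correlation.

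Over all 438 miRNAs tested, TMM and total count scaling gave opposite calls against HBEC3 for 13 in H23, 13 in H1299, 0 in Calu-1 and 0 in A549. Among the named miRNAs other than miR-10a-3p, total count scaling reversed these log2 fold changes against HBEC3, whether called or not. In H23: let-7f-5p 0.731, miR-10a-5p 0.253, miR-155-5p 0.436, miR-15a-5p 0.561, miR-16-5p 0.975, miR-182-5p 1.12, miR-194-5p 1.137, miR-21-5p 0.666, miR-210-3p 1.613 and miR-30d-5p 0.668. In H1299: miR-15a-5p 0.715, miR-16-5p 0.974, miR-183-5p 0.692, miR-194-5p 0.356, miR-21-5p 1.523, miR-221-3p 1.005, miR-30a-3p 0.822, miR-30c-5p 0.511, miR-30d-5p 0.054 and miR-92a-3p 0.825. In A549: miR-15a-5p 0.086, miR-16-5p 0.338 and miR-23b-3p 0.282. For miR-21-5p, H1299 vs HBEC3, the value was 0.046 with upper quartile scaling and -0.274 to 0.06 with a replicate left out. For miR-210-3p, Calu-1 vs HBEC3, it was -0.549 with limma-voom and -1.733 to 1.155 with a replicate left out. The cause of these reversals was not tested beyond the shift between scalings.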

Other observations

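Of the tests in this part, the strand test and its readings were chosen after its result was seen. The detection and arm-share tests were chosen after the pattern was seen. Their readings were written before their values, except for a further condition of the arm-share test that is named below. The remaining lists gave mixed results against HBEC3, and none passed by camera. Values follow the order H23, H1299, Calu-1 and A549. Counts higher and lower in the miR-17-92 and paralogous clusters, which drive proliferation, were 11 and 0, 12 and 1 (miR-92a-3p), 5 and 0, and 13 and 1 (miR-106b-3p) of 17 arms, with camera adjusted p = 0.196, 0.0771, 0.324 and 0.0736. The miR-15/16 family had 7 and 2, 7 and 2, 3 and 5, and 6 and 2 of 10 (0.475, 0.129, 0.806, 0.289), and miR-15b-5p was higher in all lines (2.00, 2.31, 2.73, 1.87). The miR-30 family had 2 and 2, 1 and 6, 1 and 4, and 1 and 4 of 11 (0.475, 0.452, 0.471, 0.271). The miR-183 cluster had 0 higher and 1, 2, 3 and 2 lower of 4 (0.734, 0.452, 0.0613, 0.139). The antifibrotic miR-29 family had 3 and 3, 4 and 3, 4 and 1, and 5 and 0 of 7 (0.734, 0.788, 0.285, 0.289). Its median was above 0 in H23 (0.50) and H1299 (0.69) while the mean (-0.13, -0.39) and the test pointed down, and 4 and 3 arms were called in H23 when adjusted over the list alone. With total count scaling medians turned from -0.41, -0.90 and -0.38 to 1.55, 0.82 and 0.71 for miR-30 in H23, H1299 and A549, and from -0.13, -0.68 and -1.03 to 1.83, 1.05 and 0.04 for the miR-183 cluster. Arms higher and lower then were 9 and 0, 6 and 0, and 5 and 1 for miR-30, and 4 and 0, 3 and 0, and 0 and 1 for the miR-183 cluster, while miR-30 in Calu-1 had 2 and 2. miR-92a-3p in H1299 turned from -0.91 to 0.825, and it was not called without HBEC3 replicate 1, 2 or 3 (edgeR adjusted p = 0.0662, 0.127 and 0.0893).

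Cell-type lists were as varied. Neuroendocrine and neuronal arms had 7 and 0, 7 and 1 (miR-375-3p), 5 and 2, and 5 and 0 of 9 (camera adjusted p = 0.143, 0.143, 0.306, 0.0901). Mesenchymal and stromal arms had 4 and 6, 6 and 2, 8 and 2, and 5 and 2 of 13 (0.475, 0.301, 0.0622, 0.928), with a median of 0.01 but a mean of -0.90 in H23, and a median of 0.07 with the test pointing down in A549. With total count scaling H23 had 7 higher and 4 lower, with a median of 1.96. Inflammation arms had 3 and 3, 4 and 2, 2 and 3, and 2 and 4 of 6 (0.848, 0.456, 0.306, 0.546), with 3 and 3 in Calu-1 when adjusted over the list alone. Total count scaling gave 3 and 1 in H23, 3 and 2 in Calu-1, and 2 and 1 in A549. Haematopoietic arms, of which 3 were tested, had camera adjusted p = 0.833, 0.788, 0.626 and 0.546. Their median in H1299 was -0.21 with a mean of 0.18, and 1.47 with total count scaling. The 14q32 list had 14 of 47 arms higher in H1299 and 17 in A549, 10 and 16 when adjusted over the list alone (0.143, 0.0736). The miR-34 and miR-449 list in H23 (0.306) and the miR-192 and miR-194 list in H23, H1299 and Calu-1 (0.734, 0.491, 0.471) did not pass. The former had 2 arms higher and 4 lower in H23, and 3 and 3 with total count scaling, and the median of the latter turned from -0.83 to 1.14 in H23 and from -1.37 to 0.36 in H1299 with total count scaling.

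Lists under 3 tested members have no test. Both Xq27 miRNAs, miR-508-3p and miR-509-3p, were lower in all lines, with 176 and 76 reads in HBEC3 and at most 3 in any cancer line. miR-224-5p had log2 values of -3.70, -2.58, 0.73 and -0.43 and the endothelial miR-126-3p of 1.38, 1.35, -4.57 and 0.36. The hepatic miR-122-5p of the serum list had 50 reads in HBEC3 and 29, 3, 81 and 8 in the cancer lines. The muscle miR-1-3p had 0 reads in HBEC3 and 186, 14, 10 and 13 in the cancer lines. Hypoxia was represented by miR-210-3p alone. In HBEC3 and these lines the C19MC list held 5, 22, 9, 0 and 37 reads and the pluripotency list 2, 5, 5, 0 and 0, with 0 members tested.

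Near-equal reads of opposite-strand miRNAs could come from counting without regard to strand. The largest absolute log2 ratio of miR-103a-3p to miR-103b and of miR-7-5p to miR-3529-3p was 0.157 over all 15 libraries, but these pairs were picked for being near-equal, so this value does not test that explanation. Of the 12 other pairs of arms at opposite-strand genes, 2 were near-equal: miR-423-5p and miR-3184-3p (7328 and 7312 reads) and miR-374b-5p and miR-374c-3p (13323 and 13007), the latter in the shared set. The other 10 were not, such as miR-203a-3p and miR-203b-5p (918878 and 2032 reads) and miR-3065-5p and miR-338-3p (20683 and 139). Which of these arms match along their whole length was not tested, so the explanation stays open. The SD over lines of the log2 ratio was 0.013 for the miR-103 pair and 0.02 for the miR-7 pair. The SD over lines of the log2 level of the pair was 0.574 and 2.949. Strands transcribed independently would not keep so constant a ratio over such changes in level. For these 2 pairs, which were picked for being near-equal, the values argue against independent transcription of the strands. Transcription of both strands in step was not tested. The levels of the near-equal miRNAs are uncertain.

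Fewer miRNAs were detected in HBEC3 and Calu-1 than in H23, H1299 and A549. Thinned to 796914 reads, the lowest library of the latter lines still exceeded the highest of the former by 104.4 ± 5.84 miRNAs (SD over 20 thinnings), which excludes library depth as the whole cause. With the 10 most abundant miRNAs left out and the rest thinned to 146308 reads, the gap was 76.2 ± 7.75, which excludes their share as the whole cause. A narrower miRNA repertoire of these lines may remain, and it was not tested.

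The higher 3p share of miR-10a in H1299 than in A549 could reflect more of every minor arm in the H1299 libraries. Over 58 other miRNA genes the median log2 difference in the ratio of minor to major arm was 0.432 (95% bootstrap interval 0.001 to 0.674), against 1.556 for miR-10a. The genes went both ways, with 37 above 0 and an SD of 1.859, which exceeds the gap of 1.124 between miR-10a and the median. Of those genes, 12 had a difference at least as large. By the reading written beforehand, which looked only at the median and its interval, these values counted against a general rise. A further condition, that the gap exceed the SD over genes, was not in that reading and was not met. With it the test cannot decide, and both a general rise and a change of miR-10a itself stay open.

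Could calls between lines come from arbitrary assignment of libraries? In each of the 10 comparisons, only 1 of 10 splits of the 6 libraries reached the observed count, which is the real one. The highest count in any other split was 1 (H1299 against Calu-1). This cannot tell, because 10 splits give no share under 0.1. For the 95 shared miRNAs, 1 of 100 groupings of the 15 libraries reached the count, the real one, and the highest other was 0. This argues against arbitrary assignment of the libraries as a whole. The other groupings mix lines, which widens the spread within a group. Their count of 0 therefore does not tell how many of the 95 could arise by chance. The test also does not separate line from medium.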
